A study of Mus musculus with 9 samples.

How the data were processed

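RNA sequencing of primary mouse articular chondrocytes was used from 9 libraries in 3 groups of 3: vehicle with DMSO, bleomycin with DMSO, and bleomycin with ST045849. Per the labels' protocols the libraries were made with a stranded poly(A) mRNA kit. Per the submitters' processing notes the reads were trimmed with Trimmomatic and aligned with STAR to GRCm38, with versions not given. The deposited values are FPKM, fragment counts scaled by exon length and library size, per gene, made by the authors. The program, the annotation and the denominator behind them are not given in the sources used here, nor is whether strand was used in counting. The labels do not say whether the 3 libraries of a group come from separate animals or cultures, so the p-values measure the spread between the samples as deposited.

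Each file listed 55450 genes by Ensembl identifier. Symbols were taken from the deposited row names. Coordinates, total exon length and exon overlap came from the GENCODE vM21 annotation. It held 99.4% of the identifiers (346 were not found) and gave a length for 99.9% of the tested genes. Identifiers that shared their symbol with another identifier numbered 234, and 0 genes of the mitochondrial chromosome were listed. Mitochondrial RNA as a sign of RNA quality was therefore not analysed here. A list of erythroid genes had 0 tested members. Genes with at least 1 FPKM in at least 3 of the 9 libraries were kept, which left 12441. Depth was read from the steps between low FPKM values multiplied by exon length, where 27.6 to 31% of values fell within 0.02 of a whole step against 4% by chance. Correlation between the libraries of a group was 0.961 to 0.979 for vehicle, 0.97 to 0.974 for bleomycin and 0.936 to 0.954 for bleomycin plus ST045849, and the first 2 principal components held 45.6 and 21.8% of the variance.

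The log2(FPKM + 1) values of all 9 libraries were fitted in 1 linear model with limma 3.58.1 in R 4.3.3, with moderated variances that follow the mean level (6 residual and 4.95 prior degrees of freedom) and p-values adjusted by Benjamini-Hochberg over the tested genes. A gene was called at an adjusted p under 0.05. All adjusted p of genes in the text are from limma. The 3 comparisons were bleomycin against vehicle, bleomycin plus ST045849 against bleomycin, and bleomycin plus ST045849 against vehicle. A gene was counted as moved back when it was called in the first 2 with opposite signs. The comparisons, the filter, the test, 15 alternatives, leaving out each of the 9 libraries and 31 gene lists were fixed before the data were examined. The lists held 599 symbols, of which 586 were matched, and 27 lists had at least 3 tested members. Lists were tested with limma's camera at a preset correlation of 0.01 between genes, and again with an estimated correlation and with fry, and adjusted over the 27 lists. A count over the list alone adjusts the same p-values over the members of that list.

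Genes are named by rule. These are the 8 largest rises and 8 largest falls among called genes whose groups lay apart, and up to 2 risen and 2 fallen members of each list by adjusted p (otherwise the member with the highest mean). A further 14 genes were fixed (Ogt, Oga, Cdkn1a, Cdkn2a, Cdkn2b, Mdm2, Mki67, Lmnb1, Il6, Mmp3, Mmp13, Col2a1, Acan and Sox9). Alternatives fixed before the data were examined were pseudocounts of 0.1 and 0.5, no filter, a mean of at least 5 FPKM, median-of-ratios scaling, quantile normalization, TPM and a block for replicate number. Others were a fit of 2 groups alone, robust and untrended variances, array weights, a change of at least 2-fold, and the estimated correlation and fry for lists. After seeing the data 8 alternatives were added. The gene length trend of each library (loess, span 0.5) was removed alone, with a block, with GC content, or without ST045849 library 1. The others were the length slope as a covariate, the fit without ST045849 libraries 2 and 3, and fits of 2 groups with a replicate block, with and without length removal. A further 5 lists were also added then.

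The replicate numbers were tested for pairing by correlating, for each pair of libraries, the deviations from the group means. Between bleomycin and bleomycin plus ST045849 the correlations of equal numbers were 0.466, 0.481 and 0.5, and each library correlated best with its own number. That comparison is therefore also given paired. The pairing comes from the data, as the labels do not state one. Across other groups unequal numbers correlated as highly, at 0.567 (ST045849 library 1 with vehicle library 2) and 0.568 (ST045849 library 2 with vehicle library 1). Such correlations therefore do not by themselves mark a shared culture. On simulated data with 100 genes changed per size and comparison, 43, 59 and 52% of 2-fold and 99, 99 and 98% of 4-fold changes were recovered, with 8, 8 and 14 false calls among 12441 genes. In the data Angptl4 and Hmox1 changed by 2.6 and 2.3 log2 units with ST045849 against bleomycin. Neither was called in the fit of 9 libraries, so these recovery rates may not hold there. Overlaps of comparisons with shared libraries were set against 100 simulated sets of unchanged groups. Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 were used for tables and figures.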

Results

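RNA was measured in primary mouse articular chondrocytes, the cells that make and maintain joint cartilage, in 3 groups of 3 libraries. The cells were kept at 3% oxygen in medium with 10% serum and received hyaluronidase at 4 U/mL for 4 h before treatment. They were then given bleomycin, a glycopeptide that breaks DNA, at 50 µg/mL for 24 h, or buffer alone. After washing, they were kept for 5 days in medium with DMSO or with ST045849 at 20 µM, renewed every 48 h. ST045849 is a small-molecule inhibitor of O-GlcNAc transferase, the enzyme (encoded by Ogt) that attaches single N-acetylglucosamine residues to nuclear and cytoplasmic proteins. The groups were vehicle with DMSO, bleomycin with DMSO, and bleomycin with ST045849. A group with ST045849 and no bleomycin was not analysed here. The series asks what inhibition of O-GlcNAcylation does to chondrocytes driven towards senescence. The deposited FPKM values covered 55450 genes per library and summed to between 340303 and 483953, and 12441 genes passed the filter and were tested. The steps between low FPKM values placed the depth of the 9 libraries between 0.875 and 1.004 times that of vehicle library 1, so depth differed little between groups. Col2a1, the main collagen of cartilage, took 4.48 to 7.07% of the FPKM sum in vehicle libraries, 3.41 to 5% with bleomycin and 2.03 to 3.74% with bleomycin plus ST045849. All fold changes are on the log2(FPKM + 1) scale, which understates the change of genes with low values, and are given with their standard error from limma (n = 3 per group).

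Bleomycin raised Cdkn1a and several genes of secreted factors and matrix-degrading enzymes. The stromelysin gene Mmp3 (chromosome 9, 7445822 to 7455975 in GRCm38) rose from 0.818 ± 0.518 FPKM (mean ± SD) in vehicle libraries to 25.4 ± 19 FPKM, a log2 change of 3.67 ± 0.52 (limma adjusted p = 0.00384). Cdkn1a, which encodes the CDK inhibitor p21 (chromosome 17, 29090976 to 29100727), rose from 140 ± 25 to 313 ± 62.3 FPKM, with a log2 change of 1.15 ± 0.28 (adjusted p = 0.0377). The collagenase gene Mmp13 rose by 2.43 ± 0.51 (adjusted p = 0.0221). The call of Mmp3 held when each of the 9 libraries was left out. The adjusted p of Cdkn1a reached 0.152 without vehicle library 2 and also missed the threshold without any other vehicle or bleomycin library or without ST045849 library 3. That of Mmp13 reached 0.101 without vehicle library 2 and also missed it without vehicle library 3 or any bleomycin library.

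Among 28 tested p53 target genes, 6 rose, none fell and 22 did not pass (15 rose when adjusted over the list alone), and 27 were higher with bleomycin. Psrc1, a microtubule-associated protein, rose by 1.51 ± 0.21 and the receptor gene Eda2r by 1.5 ± 0.24 (adjusted p = 0.00384 and 0.00673). Mdm2, which encodes the ubiquitin ligase of p53, changed by 0.63 ± 0.26 (adjusted p = 0.231). The list's median lay 0.54 above that of all genes (camera adjusted p = 2.70e-08 with the preset correlation, and adjusted p = 0.276 with an estimated correlation). The other CDK inhibitor genes did not pass, with 0.13 ± 0.26 for Cdkn2a (p16 and p19Arf; adjusted p = 0.867) and 0.37 ± 0.23 for Cdkn2b (p15; adjusted p = 0.474). Of the 35 cell cycle genes none passed over all genes or over the list alone, and 23 were lower. The proliferation marker Mki67 changed by -0.6 ± 0.38 and the lamin gene Lmnb1 by -0.67 ± 0.21 (adjusted p = 0.476 and 0.0997). As a list they were lower by camera (adjusted p = 0.0337, and adjusted p = 0.7 with an estimated correlation). None of 20 genes of double-strand break repair passed.

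Several genes of secreted factors rose. Of 31 growth factors, binding proteins and protease regulators, 11 rose and none fell (16 over the list alone), among them Spp1 (osteopontin, 2.48 ± 0.32), Igfbp2 (2.2 ± 0.24) and Plat (tissue plasminogen activator, 1.96 ± 0.23). Their adjusted p ranged from 0.00129 to 0.00283. The median of the list lay 0.88 above all genes (camera adjusted p = 3.23e-10, and adjusted p = 0.243 with an estimated correlation). Of 14 cytokines and chemokines 5 rose (6 over the list alone), including Csf1, the macrophage growth factor (1.23 ± 0.2, adjusted p = 0.00615). The camera adjusted p of that list was 0.00111, and adjusted p = 0.325 with an estimated correlation. Il6 stayed below the filter, at 0.0199 ± 0.0345 FPKM in vehicle and 0.0743 ± 0.0048 FPKM in bleomycin libraries. Of 17 matrix-degrading enzymes 7 rose and none fell (13 and 1 over the list alone), among them the aggrecanase gene Adamts5 (1.81 ± 0.26) and Mmp19 (1.74 ± 0.22; adjusted p = 0.00384 and 0.00263), with a list adjusted p of 4.15e-07 by camera and adjusted p = 0.243 with an estimated correlation. Mmp19 shares 22.3% of its exon sequence with Tmem198b on the opposite strand. Penk, the proenkephalin precursor, rose from 948 ± 277 to 6180 ± 3013 FPKM (2.63 ± 0.38, adjusted p = 0.00409), and the costimulatory gene Cd80 rose by 2.75 ± 0.22 (adjusted p = 0.000388).

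The interferon-stimulated genes stood highest of the lists. Of 25 tested, 14 rose and 11 did not pass (23 rose over the list alone), and all 25 were higher with bleomycin. The median lay 1.16 above all genes (camera adjusted p = 1.35e-15, and adjusted p = 0.276 with an estimated correlation). Isg15, a ubiquitin-like modifier, went from 1.01 ± 0.504 to 29 ± 20.4 FPKM (3.65 ± 0.63, adjusted p = 0.00894), and Ifit1, which binds foreign RNA, from 0.136 ± 0.0784 to 6.31 ± 5.12 FPKM (2.47 ± 0.38, adjusted p = 0.00553). Xaf1 rose by 1.96 ± 0.28 and the peptide transporter gene Tap1 by 1.46 ± 0.21 (adjusted p = 0.00384 and 0.00416). These 4 calls held in every leave-out fit. Of 18 NF-kB feedback targets 3 rose (3 over the list alone), including Saa3 (1.45 ± 0.23) and Tnfaip3 (1.27 ± 0.21; adjusted p = 0.00593 and 0.00769), with a camera adjusted p of 0.00842 and adjusted p = 0.358 with an estimated correlation. Macrophage markers were measured beside them: the 3 that passed the filter, Lyz2, Cd68 and Cd14, all rose. Lyz2 went from 1.2 ± 0.47 to 3.4 ± 0.0842 FPKM (1.03 ± 0.2, adjusted p = 0.0152). The list had a camera adjusted p of 0.00111 and adjusted p = 0.276 with an estimated correlation. The Lyz2 call was lost without vehicle library 2 or 3 or any bleomycin library (adjusted p up to 0.0796), and C1qa, C1qb, C1qc and Tyrobp were listed at 0 in all 3 bleomycin libraries. Of 15 fibroblast or synovial markers 4 rose (4 over the list alone), led by Thy1 (2 ± 0.37, adjusted p = 0.0126, and 0.0649 without vehicle library 2, with the call also lost without vehicle library 3 or bleomycin library 1). The list's camera adjusted p was 0.0312, and adjusted p = 0.351 with an estimated correlation.

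Amino acid and sterol genes lay lower. In the list of ATF4 and amino acid response genes, 22 of 27 were lower with bleomycin, 2 fell and 1 rose (9 and 1 over the list alone), and the median lay -0.62 from that of all genes (camera adjusted p = 5.66e-08, and adjusted p = 0.358 with an estimated correlation). The list mean was 6.122, 5.147 and 5.63 log2 units in vehicle libraries 1, 2 and 3. In bleomycin libraries 1, 2 and 3 it was 4.997, 5.238 and 5.34. The groups thus overlapped, and vehicle library 1 lay highest. The members that fell were Pycr1, of proline synthesis (-1.28 ± 0.24, adjusted p = 0.0145), and Slc7a5, a neutral amino acid transporter (-0.99 ± 0.25, adjusted p = 0.0472). The mTORC1 inhibitor gene Ddit4 rose (1.48 ± 0.35, adjusted p = 0.0371). These 3 calls were each lost in several leave-out fits. Pycr1 was lost without vehicle library 1 or 2 or bleomycin library 2 or 3 (up to 0.07) and Slc7a5 without any vehicle or bleomycin library or ST045849 library 3 (up to 0.187). Ddit4 was lost without vehicle library 2 or 3, any bleomycin library or ST045849 library 3 (up to 0.15). Outside the list, the cationic amino acid transporter gene Slc7a3 fell by 1.61 ± 0.23 (adjusted p = 0.0041), a call kept in every leave-out fit, and so did Aldh1l2 of the mitochondrial folate pathway (-1.72 ± 0.26, adjusted p = 0.0045). Of 20 cholesterol synthesis genes 17 were lower and 1, Fdps, fell (-0.93 ± 0.23, adjusted p = 0.0456, with a highest leave-out value of 0.163 without bleomycin library 1, and lost without any vehicle or bleomycin library or ST045849 library 3), with a camera adjusted p of 7.84e-05 and adjusted p = 0.276 with an estimated correlation. In the hexosamine pathway, Gfpt2, which makes glucosamine-6-phosphate, fell by 0.97 ± 0.18 (adjusted p = 0.0142, and up to 0.081 without vehicle library 3; the call was also lost without any bleomycin library), while Ogt (-0.15 ± 0.33) and Oga, which removes O-GlcNAc (0.14 ± 0.24), did not pass (adjusted p = 0.881 and 0.85).

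Cartilage genes moved in both directions. Of 30, 2 rose and 1 fell (2 and 2 over the list alone), and 20 were lower (median -0.35 from all genes, camera adjusted p = 0.0167, and adjusted p = 0.453 with an estimated correlation). Prg4, the lubricin gene of the joint surface, rose by 1.88 ± 0.23 and Prelp, a collagen-binding proteoglycan, by 1.28 ± 0.23 (adjusted p = 0.00263 and 0.0119). The call of Prelp was lost without vehicle or bleomycin library 2 or 3 (up to 0.0642). The aggrecan gene Acan stood at 1275 ± 243 FPKM in vehicle and 619 ± 73.1 FPKM in bleomycin libraries (-1.03 ± 0.28, adjusted p = 0.0652). Col2a1 changed by -0.38 ± 0.34 (adjusted p = 0.661) and the master regulator gene Sox9 by -0.27 ± 0.28 (adjusted p = 0.718). Of 12 hypertrophic and osteogenic genes 3 rose (4 over the list alone, where 1 fell), including Bglap (osteocalcin, 1.7 ± 0.22, adjusted p = 0.00283). The list did not pass by camera (adjusted p = 0.22) but was higher by fry (adjusted p = 0.0227). The camera adjusted p was 0.0039 for the lysosome list (higher, 0 of 23 passing, and adjusted p = 0.276 with an estimated correlation). It was 0.0434 for glycolysis (lower, 1 of 22 fell, and adjusted p = 0.499 with an estimated correlation) and 0.0167 for oxidative phosphorylation (lower, 0 of 31, and adjusted p = 0.7 with an estimated correlation). The lists for TGF-beta targets, NRF2 genes, heat shock, unfolded protein response, aryl hydrocarbon receptor, glutamine, CDK inhibitors, hexosamine pathway, DNA repair, osteoclast and skeletal muscle did not pass by camera (adjusted p from 0.0864 to 0.991). By fry those for TGF-beta targets and the aryl hydrocarbon receptor were higher (adjusted p = 0.01055 and 0.00464). For CDK inhibitors, DNA repair and skeletal muscle the median was above 0 and camera's direction down. For glutamine the median was 0.12 and the mean -0.1.

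In total 607 genes changed with bleomycin, 523 up and 84 down, of which 350 changed at least 2-fold. In 3478 of 12441 genes the 3 libraries of each group lay apart (10% by chance). With ST045849 against bleomycin, where 0 genes were called, 3135 did, so this count does not by itself mark an effect. The share of rises depended on the scale: 351 rose and 141 fell after median-of-ratios scaling and 316 and 151 after quantile normalization. These scalings took the median of all genes from 0.1 to -0.02 and -0.03. After scaling to TPM 548 rose and 83 fell, with a median of all genes of 0.13. The 8 largest rises also held Msmp (4.47 ± 0.58) and Pcdhga2 (3.11 ± 0.52; adjusted p = 0.00283 and 0.00787), both uncertain: all of the exon sequence of Msmp lies within Rgp1 on the opposite strand, whose own level was 19.6 FPKM in both groups, and Pcdhga2 shares 45.1% of its exon sequence with other gamma-protocadherins. Among the 8 largest falls, besides Slc7a3 and Aldh1l2, were Klk10 (a serine protease, -2.03), Gask1a (-1.86), B4galnt2 (a glycosyltransferase, -1.86), Avil (an actin-binding protein, -1.83) and Ppp1r1b (-1.74), with adjusted p between 0.00324 and 0.0226. The call of Gask1a was lost without vehicle library 2 or 3 or any bleomycin library (up to 0.0946). Leaving out single libraries gave 334, 184 and 206 genes (vehicle 1, 2 and 3), 250, 202 and 262 (bleomycin 1, 2 and 3) and 829 without ST045849 library 1, with 782 and 618 without its libraries 2 and 3.

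**Figure D1:**
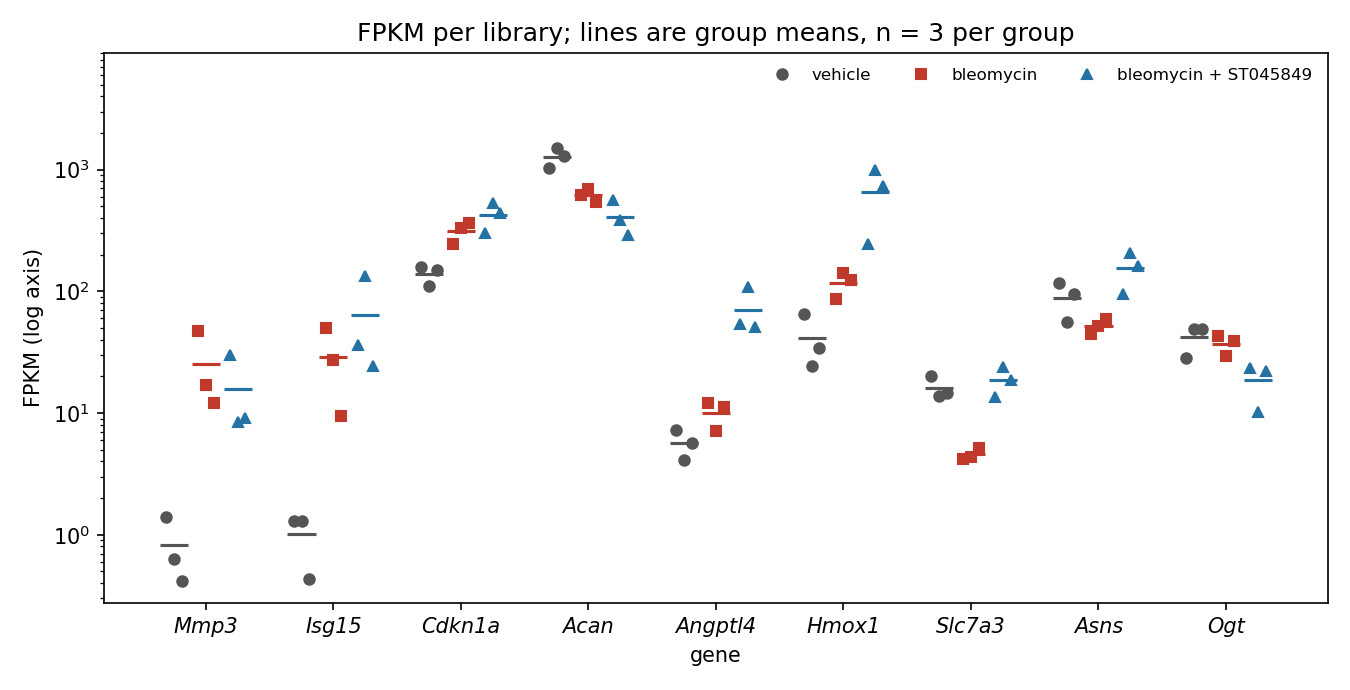
FPKM (log axis) of 9 named genes in each library, with points for the 3 libraries of each group and lines for group means. Mmp3 lay at 1.4 FPKM or below in vehicle libraries and at 8.39 FPKM or above in the other 6, while Slc7a3 stood at 16.2 FPKM in vehicle, 4.57 FPKM in bleomycin and 18.6 FPKM in bleomycin plus ST045849 libraries (means).

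Cells given bleomycin and ST045849 were compared with cells given bleomycin alone. Genes of amino acid supply, the antioxidant response and mitochondrial respiration were higher with the inhibitor as lists, and genes of cholesterol synthesis and matrix were lower, each with the preset correlation only (adjusted p from 0.479 to 0.565 with an estimated correlation). No single gene passed over all 12441 in limma's fit of all 9 libraries, where 2804 had an unadjusted p under 0.05. With the length slope as a covariate, chosen after seeing the data, 217 of 12432 did. That slope itself lay apart between the 2 groups. In 3135 of 12441 genes the 3 libraries of each group lay apart (10% by chance). Slc7a3 stood at 4.57 ± 0.503 FPKM with bleomycin and 18.6 ± 5.16 FPKM with bleomycin plus ST045849 (1.78 ± 0.23, adjusted p = 0.0662). Asns, the asparagine synthetase gene, stood at 52.1 ± 7.4 and 154 ± 56.2 FPKM (1.49 ± 0.33, adjusted p = 0.203) and Hmox1, the heme oxygenase gene, at 117.2 ± 27.5 and 661 ± 385 FPKM (2.29 ± 0.5, adjusted p = 0.203). The smallest adjusted p, 0.0505, belonged to Angptl4, an inhibitor of lipoprotein lipase (2.64 ± 0.31). Ogt itself, on chromosome X (101640060 to 101684351), stood at 36.9 ± 6.86 and 18.7 ± 7.28 FPKM (-1.01 ± 0.33, adjusted p = 0.203), and Oga changed by -0.21 ± 0.24 (adjusted p = 0.581). Ogt and the other fixed genes apart, the genes named in this comparison were picked by the highest mean level in their list (Nupr1, Ftl1, Fn1, Asns) or after their values were seen.

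In the data the libraries of these 2 groups went together by replicate number (correlations of 0.466, 0.481 and 0.5 between equal numbers). Unequal numbers reached 0.567 and 0.568 between bleomycin plus ST045849 and vehicle, so the pairing is not certain. A fit of the 2 groups with the pair as a block, chosen after seeing the data, called 2403 genes, 1408 up and 995 down. The same block in the fit of all 9 libraries called 0 (limma, with 2804 genes at an unadjusted p under 0.05 without it). In that paired fit of 2 groups 23 of 27 ATF4 and amino acid response genes rose and none fell, as did 13 of 24 NRF2 and antioxidant genes with 1 fall, and 16 of 31 oxidative phosphorylation genes. Its calls followed gene length, with a median exon length of 1725 bases among the genes that rose and 8594 bases among those that fell. With the length trend of each library removed in the same paired fit, 173 genes passed, 80 up and 93 down. Their median exon length was 5875 bases among the rises and 2459 bases among the falls, so a relation with length remained, in the other direction. Among the rises were 13 of the 27 ATF4 genes, 4 of the 24 NRF2 genes and 0 of 31 oxidative phosphorylation genes. Those 13 were Atf4 itself (1.36 ± 0.26), Asns (1.24 ± 0.18), Psat1 and Phgdh of serine synthesis (1.31 ± 0.16 and 1.34 ± 0.18), and Cth of cysteine synthesis (1.48 ± 0.19). The others were Slc7a5 and Slc3a2, which pair in an amino acid transporter (1.07 ± 0.17 and 1.04 ± 0.2), and Trib3, Chac1, Mthfd2, Nupr1, Aars and Pck2 (0.87 to 1.43), with limma adjusted p from 0.0305 to 0.0491. The NRF2 genes were Hmox1 (1.9 ± 0.21), Gsta4, Fth1 and Pgd. In the same fit Mmp3 and Htra1 of the matrix-degrading list fell by 1.04 ± 0.18 and 0.91 ± 0.16 (adjusted p = 0.0436 and 0.0453). Without length removal the paired falls were 0.66 ± 0.19 and 0.68 ± 0.19 (adjusted p = 0.0369 and 0.0359), and in the fit of all 9 libraries Mmp3 changed by -0.66 ± 0.52 (adjusted p = 0.425). With length removed the sphingomyelinase gene Smpd3 fell by 2.09 ± 0.24 (adjusted p = 0.0305). Ogt passed in the paired fit without length removal (-1.01 ± 0.2, adjusted p = 0.0169) and not with it (-0.76 ± 0.17, adjusted p = 0.0591). With length removed Acan (0.172) and Col2a1 (0.911) did not pass. Only 2 residual degrees of freedom stand behind these fits: without pair 1, 2 or 3 they called 4237, 216 and 294 genes, and 1735, 3 and 65 with the length trend removed.

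By list, in the fit of all 9 libraries, the ATF4 and amino acid response genes had 26 of 27 members higher, 0 passing over all genes and 20 rising when adjusted over the list alone, with a median 1.01 above all genes (camera adjusted p = 2.18e-11, and adjusted p = 0.479 with an estimated correlation). The NRF2 and antioxidant list had 13 rises and 1 fall over the list alone and a median 0.55 above all genes (camera adjusted p = 1.01e-06, and adjusted p = 0.479 with an estimated correlation). The ferritin light chain gene Ftl1 changed by 1.49 ± 0.4 and the glutathione transferase gene Gsta4 by 1.72 ± 0.36. All 31 nuclear-encoded oxidative phosphorylation genes were higher, none of them passing over the list alone, with a median 0.6 above all genes (adjusted p = 4.71e-07, and adjusted p = 0.565 with an estimated correlation). The lysosome list was also higher (median 0.22 above all genes, adjusted p = 0.0361, and adjusted p = 0.479 with an estimated correlation). That call was lost after each of the 3 scalings, with the direction turned by quantile normalization (adjusted p = 0.631), and in the paired fit of 2 groups (0.0736). Cholesterol synthesis genes were lower (-0.42 from all genes, adjusted p = 0.00298, and adjusted p = 0.479 with an estimated correlation). So were TGF-beta targets (-0.49, 0.0131, with 2 falls over the list alone) and fibroblast or synovial markers (-0.59, 0.00977, with 2 falls over the list alone), including the fibronectin gene Fn1 (-1.07 ± 0.3, adjusted p = 0.203). Cartilage matrix genes (-0.31, 0.029) and matrix-degrading enzymes (-0.45, 0.0361) were lower too, with 0 members passing over either list alone. With an estimated correlation these 4 lists had adjusted p = 0.479, 0.479, 0.565 and 0.548. With the length slope as a covariate, a setting chosen after seeing the data, the direction turned for oxidative phosphorylation, cartilage matrix and matrix-degrading enzymes (adjusted p = 0.272, 0.859 and 0.656). The aggrecan gene Acan changed by -0.63 ± 0.28, Col2a1 by -0.27 ± 0.34, Sox9 by -0.57 ± 0.28, Mmp13 by -0.25 ± 0.51 and Cdkn1a by 0.42 ± 0.28 (adjusted p from 0.218 to 0.767).

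Of the lists that bleomycin had raised by camera, p53 targets (0.389), interferon response (0.677), cytokines (0.929), secreted growth factors (0.0949), NF-kB feedback targets (0.389) and macrophage markers (0.465) did not pass in this comparison. As given above, matrix-degrading enzymes and fibroblast or synovial markers were lower, and the lysosome list was higher still (fry adjusted p = 0.0469). Of the lists it had lowered, ATF4 and oxidative phosphorylation genes were higher, while cholesterol synthesis and cartilage matrix genes were lower still. The shared bleomycin libraries can give opposite directions without any effect. With the replicate block in the fit of all 9 libraries, secreted growth factors and hypertrophic genes were lower (both camera adjusted p = 0.0356, and adjusted p = 0.474 with an estimated correlation). With the length trend removed, chosen after seeing the data, secreted growth factors (0.00314), hypertrophic genes (0.00143) and cell cycle genes (0.0228) were lower. With a replicate block added to that fit, camera's adjusted p with an estimated correlation was 0.2275, 0.2275 and 0.5129. In the paired fit with length removed these 3 and cytokines were lower (0.00164, 0.000275, 0.0267 and 0.0121, and adjusted p = 0.498, 0.498, 0.571 and 0.498 with an estimated correlation). In the other lists, without these changes, camera's adjusted p ranged from 0.0663 for hypertrophic and osteogenic genes to 0.977 for aryl hydrocarbon receptor targets, and for those targets, the cytokines and the hexosamine pathway the median was above 0 and camera's direction down. The senescence-associated Cdkn2a and Cdkn2b stood at 9.76 ± 1.41 and 51.2 ± 5.85 FPKM with the inhibitor against 5.26 ± 1.39 and 29 ± 4.22 FPKM without it (0.8 ± 0.26 and 0.8 ± 0.23, both adjusted p = 0.203). In the paired fit of 2 groups Cdkn2a and Cdkn2b rose and Mki67 fell (adjusted p = 0.0265, 0.0219 and 0.0397), and none of these 3 passed with the length trend removed (0.241, 0.168 and 0.413). In the fit of all 9 libraries Mki67, Lmnb1 and Mdm2 changed by -0.69 ± 0.38, -0.03 ± 0.21 and -0.1 ± 0.26 (adjusted p from 0.271 to 0.937).

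The inhibitor libraries differed among themselves by gene length. Short genes were higher and long genes lower in ST045849 libraries 2 and 3, with slopes of -0.21 and -0.14 log2 units per doubling of exon length, against 0.02 in library 1, 0.04 to 0.1 with bleomycin alone, and -0.07, 0.1 and 0.08 in vehicle libraries 1, 2 and 3. Across genes the change with ST045849 correlated with exon length at a Spearman rho of -0.6 (genes are not independent replicates). The share of ribosomal protein genes in the FPKM sum moved likewise, at 13.3 and 11.2% in these libraries, 7.93% in ST045849 library 1 and 6.7 to 7.64% with bleomycin alone, but it was highest in vehicle library 1 (13.7%), with 9.24 and 9.79% in vehicle libraries 2 and 3. Small noncoding RNA genes held 3.72 and 5.41% of the FPKM sum in ST045849 libraries 2 and 3, and 1.85 to 2.81% in the other 7. Some short genes lie within exons of abundant mRNAs. Gm22133, which covers 8.1% of the Ftl1 exon sequence on the same strand, stood at 1868, 2358 and 8594 FPKM in vehicle, bleomycin and bleomycin plus ST045849 libraries (means). How much such overlaps add to these shares was not tested. Leaving out ST045849 library 1 gave 2225 genes instead of 0, with 1332 up and 893 down at median exon lengths of 1852 and 8362 bases, and leaving out its library 2 gave 3 genes (Kirrel, Pcdhgb4 and Angptl4). The medians of the oxidative phosphorylation and ATF4 lists went from 0.66 and 1.07 to 0.36 and 0.92 with the length trend removed in the fit of all 9 libraries. The scale moved the median of all genes from 0.06 to -0.19 when values were scaled to TPM.

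**Figure D2:**
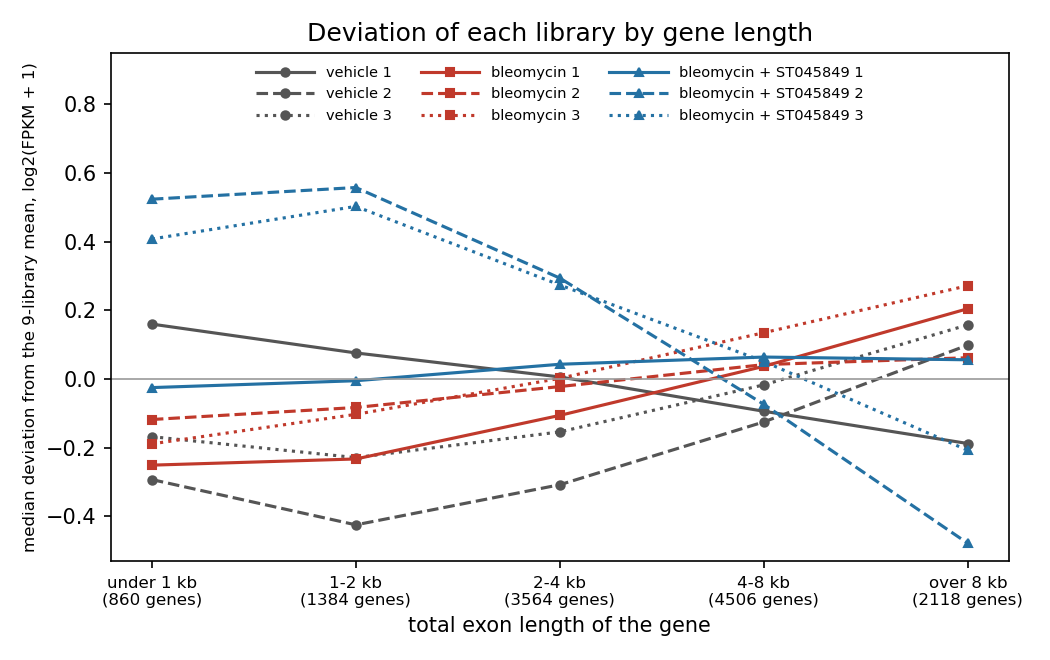
Median deviation of each library from the mean of the 9 libraries, in log2(FPKM + 1), for genes grouped by total exon length. In genes of 1 to 2 kb, ST045849 libraries 2 and 3 lay 0.56 and 0.5 above the mean and library 1 at -0.01, and in genes over 8 kb they lay at -0.48 and -0.21.

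Cells given bleomycin and ST045849 were also compared with vehicle. Hmox1 (chromosome 8, 75093621 to 75100589) rose from 41.3 ± 21.3 to 661 ± 385 FPKM, a log2 change of 3.86 ± 0.5 (adjusted p = 0.00214), and Angptl4 from 5.66 ± 1.54 to 70.9 ± 31.8 FPKM (3.37 ± 0.31, adjusted p = 0.000919). Isg15 rose to 64.4 ± 59.2 FPKM (4.68 ± 0.63, adjusted p = 0.0024) and Mmp3 to 15.8 ± 12.3 FPKM (3.01 ± 0.52, adjusted p = 0.00687). Acan fell from 1275 ± 243 to 412 ± 135 FPKM (-1.66 ± 0.28, adjusted p = 0.00657), and Papss2, which makes the sulfate donor for proteoglycans, from 246 ± 57.7 to 55.2 ± 31.9 FPKM (-2.25 ± 0.34, adjusted p = 0.00413). These 6 calls held in every leave-out fit. Ogt fell by 1.16 ± 0.33 (adjusted p = 0.047), a call kept only without vehicle library 1 or ST045849 library 1 and otherwise lost, with values up to 0.178 without vehicle library 2.

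Of 28 p53 target genes 14 rose (16 over the list alone), led by Perp, a desmosome-associated membrane protein (2.3 ± 0.31), and Psrc1 (1.66 ± 0.21; adjusted p = 0.00227 and 0.00215). The list was higher (camera adjusted p = 1.68e-06, and adjusted p = 0.393 with an estimated correlation). Cdkn1a rose by 1.57 ± 0.28 (adjusted p = 0.0072), kept in every leave-out fit, and Cdkn2b by 1.17 ± 0.23 (adjusted p = 0.0118, and 0.0568 without vehicle library 2, and lost in 2 of 3 fits with the length trend removed). Cdkn2a rose by 0.93 ± 0.26 (adjusted p = 0.0443), but not after any of the 3 scalings or with the length trend removed, nor without library 2 or 3 of any group (up to 0.186 without vehicle library 2). Of 25 interferon-stimulated genes 19 rose (22 over the list alone), with Irf9, a subunit of the interferon-activated transcription factor, at 1.67 ± 0.2 and Xaf1 at 2.34 ± 0.28 (list adjusted p = 3.08e-10, and adjusted p = 0.393 with an estimated correlation). NRF2 and antioxidant genes rose in 10 of 24 cases (17 over the list alone; list adjusted p = 1.01e-05, and adjusted p = 0.399 with an estimated correlation), among them Gsta4 (3.02 ± 0.36, adjusted p = 0.00142). Of 23 lysosome genes 8 rose (15 over the list alone), including the hexosaminidase gene Hexa (1.11 ± 0.19, adjusted p = 0.00657), with a list adjusted p of 8.62e-05 and adjusted p = 0.246 with an estimated correlation. Secreted growth factors and protease regulators rose in 12 of 31 cases (16 over the list alone; 9.31e-05), cytokines in 6 of 14 (6; 0.012, and 0.11 with the length trend removed) and matrix-degrading enzymes in 5 of 17 with 1 fall (8 and 1; 0.0109), in each with the count over the list alone and the camera adjusted p in brackets. With an estimated correlation these 3 had adjusted p = 0.393, 0.439 and 0.399.

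The cartilage list held 6 falls and 4 rises among 30 genes (12 and 4 over the list alone; median -0.78 from all genes, camera adjusted p = 0.000179, and adjusted p = 0.393 with an estimated correlation). Besides Acan, the matrilin gene Matn3 fell by 1.8 ± 0.34 (adjusted p = 0.0097, and 0.0542 without vehicle library 2). Prg4 rose by 1.64 ± 0.23 (adjusted p = 0.00322) and Mia by 2.06 ± 0.41 (adjusted p = 0.0127). The call of Mia was lost without vehicle library 2 or 3 (up to 0.0603) and is uncertain, since Mia shares 41.2% of its exon sequence with Gm21983. Col2a1 (-0.65 ± 0.34) and Sox9 (-0.84 ± 0.28) did not pass (adjusted p = 0.212 and 0.0763). All 20 cholesterol synthesis genes were lower and 3 fell (7 over the list alone), with a list adjusted p of 3.43e-09 and adjusted p = 0.246 with an estimated correlation. Of 35 cell cycle genes 2 rose, Ccne1 (1.13 ± 0.24) and E2f1 (0.76 ± 0.17), which drive entry into S phase, while 23 were lower and the list lay lower (camera adjusted p = 0.00277, and adjusted p = 0.599 with an estimated correlation). Both calls were lost without vehicle library 2 or 3 or ST045849 library 3 (up to 0.0842 and 0.106), and that of E2f1 with each of the 3 scalings. Mki67 changed by -1.29 ± 0.38 and Lmnb1 by -0.7 ± 0.21 (adjusted p = 0.0528 and 0.0569). The ATF4 list, 25 of whose 27 members were higher than in vehicle libraries, did not pass (camera adjusted p = 0.0559; 2 members rose, also over the list alone), and passed with the length trend removed (adjusted p = 0.0302), a setting chosen after seeing the data. Without that removal it had adjusted p = 0.661 with an estimated correlation and 0.21 by fry.

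Oxidative phosphorylation was higher as a list with 0 of 31 genes passing, also over the list alone (camera adjusted p = 0.0101, and adjusted p = 0.618 with an estimated correlation). With the length trend removed its median went from 0.53 to 0.13 and the call was lost (adjusted p = 0.241). DNA repair (1 of 20 fell, 0 over the list alone) and glycolysis (2 of 22 fell, 1 over the list alone) were lower, both with a camera adjusted p of 0.0202, and adjusted p = 0.439 and 0.5 with an estimated correlation. The DNA repair call was lost with the length trend removed (adjusted p = 0.0651). All 3 macrophage markers rose (camera adjusted p = 0.00383, and adjusted p = 0.393 with an estimated correlation). The remaining lists did not pass by camera (adjusted p from 0.0559 to 0.616). By fry CDK inhibitors (adjusted p = 0.0122, 3 of 7 rose), aryl hydrocarbon receptor targets (0.00594), osteoclast markers (0.0327) and NF-kB feedback targets (0.0381) were higher. For hypertrophic and osteogenic genes, TGF-beta targets, fibroblast markers, glutamine and the unfolded protein response the median was above 0 and camera's direction down, and for the hexosamine pathway the median was 0.02 and the mean -0.04. The kinase gene Nrk (-3.22 ± 0.67) and the imprinted Zim1 (-2.89 ± 0.64) and Peg3 (-1.81 ± 0.49) were among the 8 largest falls (adjusted p = 0.0156, 0.0208 and 0.0412). Nrk and Zim1 lost their calls without vehicle or ST045849 library 2 or 3 (up to 0.0804 and 0.0962), and Peg3 in addition without bleomycin library 3 (up to 0.159) and after 2 of the 3 scalings.

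In total 1225 genes changed against vehicle, 1009 up and 216 down, with 653 at least 2-fold and 3442 of 12441 genes with the groups apart (10% by chance). The median exon length was 2834.5 bases among the rises and 6871.5 bases among the falls, and 779 genes passed with the length trend removed. The split was 495 up and 368 down after median-of-ratios scaling, 518 and 322 after quantile normalization and 493 and 217 after scaling to TPM, which took the median of all genes from 0.19 to -0.004, 0.02 and -0.03. Leaving out single libraries gave 1883, 286 and 351 genes (vehicle 1, 2 and 3) and 3060, 623 and 611 genes (ST045849 1, 2 and 3). With ST045849 represented by library 1 alone, so that its spread is taken from the other groups, 154 genes were called, 137 of them shared with the fit of all 9 libraries.

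**Figure D3:**
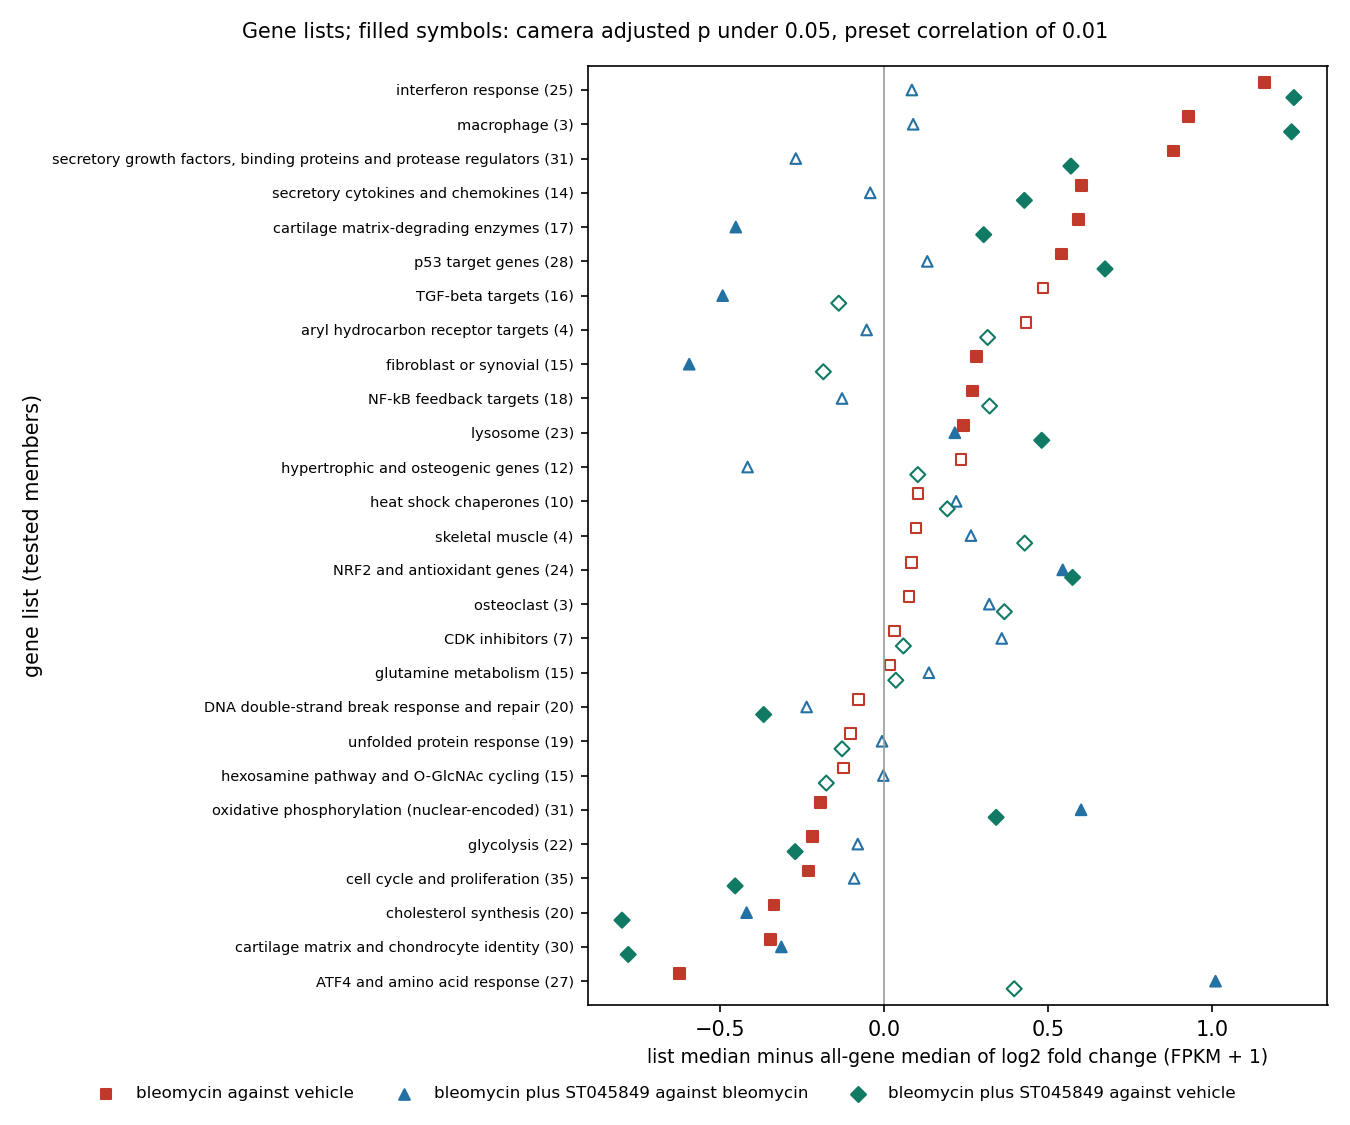
Median log2 fold change of each gene list minus that of all tested genes (axis in log2 units) in the 3 comparisons, filled where camera's adjusted p was under 0.05 with the preset correlation. The ATF4 and amino acid response list lay at -0.62 with bleomycin against vehicle and at 1.01 with ST045849 against bleomycin, while the interferon list lay at 1.16 and 0.09. The ATF4 list mean was 6.122 in vehicle library 1 against 5.147 and 5.63 in vehicle libraries 2 and 3, and vehicle and bleomycin libraries overlapped.

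Whether ST045849 moved bleomycin's changes back was counted from both comparisons, which share the bleomycin libraries. In the fit of all 9 libraries no gene passed in both with opposite signs, against 0.11 in 100 simulated sets of unchanged groups, since none passed with the inhibitor (0 by limma, 2804 at an unadjusted p under 0.05). The fold changes of the 2 comparisons correlated across genes at -0.27, against -0.43 in the simulations (-0.91 to 0.26), and their covariance was -0.06 against -0.04, a difference of -0.01. The 523 genes that rose with bleomycin had a median change of 1.082 against vehicle, and 1.025 with bleomycin plus ST045849. Against bleomycin 311 of them were lower with ST045849 (median -0.107). The 84 that fell had medians of -0.996 and -0.89, and 59 were higher against bleomycin (median 0.213). Such genes were picked in a comparison that shares the bleomycin libraries, which alone can give some opposite change. The count of genes moved back was 156 without ST045849 library 1. In fits of 2 groups with a replicate block it was 111 (96 rose with bleomycin and 15 fell), and 26 with the length trend removed as well (18 and 8). There 26 and 4 genes passed in the same direction in both comparisons. Independent lists give 54.8 and 13, and 4.9 and 2.5 with length removed, but libraries shared with opposite sign can raise such counts without any effect. These settings also block bleomycin against vehicle, where the numbers do not pair the libraries, so part of the counts may come from the shared bleomycin libraries. The 2 comparisons against vehicle called 373 genes up and 56 down in both and 0 in opposite directions, where independent lists give 42.4 and 1.5 and simulations of unchanged groups with the shared vehicle libraries a mean of 1.4 (429 observed in all). Part of the excess over independent lists may come from the shared vehicle libraries. The fold changes correlated at 0.552, against 0.5 in simulations (-0.148 to 0.901), with a covariance of 0.132 against 0.0485 (-0.00854 to 0.127), a difference of 0.0837.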

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

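For bleomycin against vehicle the count of 607 genes became 284 with a mean of at least 5 FPKM, 1024 in a fit of 2 groups alone, 1938 with array weights and 350 at 2-fold or more. In settings chosen after seeing the data it was 1233 with the length slope as a covariate, 1025 without ST045849 libraries 2 and 3, and 1046 with 2 groups, length removal and a replicate block. Leaving out 1 library took it from 184 (vehicle 2) to 829 (ST045849 1). For bleomycin plus ST045849 against bleomycin the count of 0 became 1 with no filter (Pgpep1l), 2 with a mean of at least 5 FPKM, quantile normalization or array weights, and 2225 without ST045849 library 1. Settings chosen after seeing the data gave 2 with the length trend or the length and GC trends removed (in each of these Angptl4 and Slc7a3), 2 without ST045849 libraries 2 and 3 (Pcdhgb4 and Gm27671), 565 with the length trend removed and no ST045849 library 1, and 2403 and 173 in the paired fits of 2 groups without and with length removal. Against vehicle the 1225 genes of bleomycin plus ST045849 became 651 with no filter, 660 with a mean of at least 5 FPKM, 710 with TPM, 621 in a fit of 2 groups alone, 2767 with array weights and 653 at 2-fold or more, and went from 286 without vehicle library 2 to 3060 without ST045849 library 1. Settings chosen after seeing the data gave 779 with the length trend removed, 359 with the slope as a covariate, 154 without ST045849 libraries 2 and 3, and 199 and 241 in the blocked fits of 2 groups without and with length removal. Genes moved back, 0 in the planned fit, numbered 1 with a mean of at least 5 FPKM, quantile normalization, array weights, the length trend removed, the length and GC trends removed, or no ST045849 libraries 2 and 3. They numbered 99, 111 and 26 with the length trend removed and no ST045849 library 1 and in the paired fits without and with length removal, and 156 without ST045849 library 1. The blocked counts also block bleomycin against vehicle, where the numbers do not pair the libraries. Fits without ST045849 libraries 2 and 3 hold 1 library with ST045849 and take its spread from the other groups. With an estimated correlation 0 lists passed in each comparison, against 15, 9 and 14 with the preset one. By fry 12, 1 and 13 lists passed. For bleomycin against vehicle these held the interferon (fry adjusted p = 0.0132), p53 (0.01055), secreted growth factor and matrix-degrading lists (both 0.003365). The ATF4 (0.316), cartilage (0.711) and cell cycle (0.837) lists did not pass by fry there. With ST045849 against bleomycin, 14 lists passed with no filter, 5 without ST045849 libraries 2 and 3, and 1 by fry. In that comparison the direction turned for matrix-degrading enzymes with the slope as a covariate (adjusted p = 0.656) and without ST045849 libraries 2 and 3 (0.809), for cartilage matrix (0.859) and oxidative phosphorylation (0.272) with the slope as a covariate, and for the unfolded protein response (0.0251) and lysosome (0.631) lists with quantile normalization. Against vehicle it turned for oxidative phosphorylation with the slope as a covariate (0.179) and without ST045849 libraries 2 and 3 (0.33). It also turned for Atr, at 0.13 (adjusted p = 0.726), with the length trend removed and no ST045849 library 1. A replicate block in the fit of 9 libraries gave 733, 0 and 1386 genes and 15, 11 and 14 lists, all within 1.5 times of the counts without it. In the comparisons with vehicle the libraries share only a number (correlations of -0.071, -0.026 and 0.546 for bleomycin, and -0.519, -0.279 and 0.424 for bleomycin plus ST045849). Of 52 named calls with bleomycin, 46 held in all 3 scalings, 29 in all 9 leave-out fits, 48 with the length trend removed and 23 in all other alternatives fixed beforehand. Of 68 with bleomycin plus ST045849 against vehicle 52, 28, 51 and 29 did.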

Other observations

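The lists of this paragraph and the next were drawn up after the results were seen. Of 24 PPAR target genes, which serve lipid uptake and fatty acid oxidation, 16 rose with bleomycin plus ST045849 against vehicle, among them Pdk4 (1.53 ± 0.18), Cpt1a (1.37 ± 0.2) and Plin2 (1.39 ± 0.25; limma adjusted p = 0.00136, 0.00393 and 0.00891). As a list they were higher there (camera p = 2.32e-10, and p = 0.0152 with an estimated correlation), in a comparison that holds bleomycin and ST045849 together. With bleomycin alone 5 rose (camera p = 0.000778, and p = 0.125 with an estimated correlation). With ST045849 against bleomycin none passed by itself and the list was higher (camera p = 1.51e-07, and p = 0.0318 with an estimated correlation). Without Angptl4, Cpt1b and Cidea, which had prompted it, camera gave 2.87e-05 and 0.0574. Against vehicle camera gave 5.41e-08 and 0.0225 without them. Fabp4, the only tested adipocyte marker and also a member of the list, changed by 0.83 ± 0.29 with ST045849 against bleomycin (limma adjusted p = 0.203) and rose by 1.17 ± 0.29 against vehicle (0.0311). A hypothesis is a lipid-handling response to ST045849, which a camera p of 0.0574 with an estimated correlation leaves open; adipocytes in the culture were not tested as a cause.

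Imprinted genes lay lower with bleomycin by camera with the preset correlation only (29 tested, camera p = 0.00221, p = 0.0678 with an estimated correlation, fry p = 0.1235). The H19 noncoding RNA fell from 4581 ± 834 to 1627 ± 121 FPKM (-1.48 ± 0.27, limma adjusted p = 0.0119), as did Meg3 (-1.06 ± 0.25), Mirg, Usp29 and Magel2, while Dio3 rose by 2.01 ± 0.26 and Slc22a18 by 0.84 ± 0.21. Without H19, Zim1 and Peg3 camera gave 0.0315 and 0.13. Of 26 genes of sulfate and nucleotide sugar supply 3 fell with bleomycin, among them Papss2 (-1.51 ± 0.34) and Slc35d1 (-1.06 ± 0.17), with a camera p of 1.74e-05 and p = 0.0728 with an estimated correlation. Of 34 listed replication-dependent histone genes only 9 were tested, in libraries made with a kit that selects RNA with a poly(A) tail. Of these 9, 3 rose with bleomycin (camera p = 3.73e-06, and p = 0.116 with an estimated correlation). None of 68 ribosomal protein genes passed in any comparison (0 by limma), with medians of -0.64, 0.87 and 0.25. As a list they were lower with bleomycin (camera p = 3.78e-23, p = 0.141 with an estimated correlation, fry p = 0.115). With ST045849 against bleomycin they were higher (camera p = 2.44e-18, p = 0.186 with an estimated correlation, fry p = 0.0426). Bleomycin plus ST045849 against vehicle gave a camera p of 0.822.

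Of the tests on the shift of short and long genes in ST045849 libraries 2 and 3, only that against treatment was chosen after the result was seen. With GC content in the regression 93.1% of the slope difference remained, and without ribosomal protein genes and genes under 600 bases 152% did, so neither accounts for it. The slopes of the 3 libraries with ST045849 and the 3 with bleomycin alone gave an exact permutation p of 0.1, the smallest that 3 against 3 can give. Paired by replicate number, also after the result was seen, the slope differences were -0.078, -0.25 and -0.231. All 3 were negative, but 3 pairs cannot give an exact p under 0.25. Treatment and a state of single libraries cannot be told apart.

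All tests on the ATF4 and amino acid response genes were chosen after the result was seen. Their median change with ST045849 was 1.07, and 0.92 with the length trend removed, so gene length does not account for it. Within groups the list mean followed the length slope (Pearson r = -0.921, exact permutation p = 0.0139, and Spearman rho = -0.917, exact permutation p = 0.0278, with 9 libraries, 216 permutations and 1 relation tested). With the points of ST045849 libraries 2 and 3 dropped r was -0.901. There library 1 was still centred on the mean of all 3, so that value still draws on the 2 dropped libraries. A state of single cultures that moves both could give such a relation. The 3 paired differences were 0.75, 1.4 and 1.06, where 3 pairs cannot give an exact p under 0.25, and the unpaired exact permutation p was 0.1. An effect of ST045849 and such a state cannot be told apart.

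Both tests on the interferon genes with bleomycin were chosen after the result was seen. Over 6 abundant macrophage transcripts the median of the mean FPKM with bleomycin was 0, since C1qa, C1qb, C1qc and Tyrobp were listed at 0. This argues against macrophages in the culture as the source of the rise. The 3 tested macrophage markers rose, however (camera adjusted p = 0.00111), so macrophages are not excluded. The list's median change was 1.26, and 1.1 with the length trend removed. An interferon response of the chondrocytes themselves to bleomycin is a hypothesis. The list passed by fry (adjusted p = 0.0132) but not by camera with an estimated correlation (adjusted p = 0.276), which leaves the hypothesis open.

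The regroupings of libraries were planned before the results were seen. With 10 splits of 3 against 3 no share under 0.05 can be reached. For bleomycin against vehicle the real split gave 607 genes and the highest other 2, so 1 of 10 splits gave as many. For ST045849 against bleomycin all 10 of 10 gave 0, including the 4 that part all 3 pairs. In the paired fit of 2 groups, chosen after the result was seen, the real grouping gave 2403 genes, or 173 with the length trend removed, and each of the 3 others that swap 1 pair gave 0. So few groupings cannot give a share under 0.05 either. For bleomycin plus ST045849 against vehicle 1 of 10 gave 1225 or more, and the highest other, 588 genes, set vehicle library 1 with ST045849 libraries 2 and 3, the 3 libraries with negative length slopes, against the rest.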
